A study of Drosophila melanogaster with 2 samples.

How the data were processed

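The samples were whole Drosophila melanogaster embryos, 0 to 24 h old, of a line that expresses MBD-R2 fused to eGFP. Chromatin was sonicated to fragments of 200 to 800 bp and precipitated with an antibody against GFP, per the labels. The labels number 2 biological replicates of 1 group, from separate biological samples. Control libraries are named in the labels and were not analysed here.

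The deposited files are peak lists on the dm6 assembly, per the file headers and per the labels. Each replicate has a ranked list of peaks and a list thresholded on the irreproducible discovery rate (IDR), which measures how consistently a peak ranks between compared lists. For the series there is a main thresholded list, a conservative thresholded list and 2 rankings. The aligner, the peak caller, their versions and the depth of the libraries are not given in the sources used here, so the depth behind a peak is unknown. The signal value of each peak was set by the authors' peak caller, and its scaling is not stated. It was used to rank and filter peaks, to compare medians of log2 signal between classes of peaks within a list, and for ratios between the replicates' lists, which are not normalised for depth. Shifts and ratios are read as if the signal were linear in enrichment, which is not known. The score deposited by the authors is a scaled IDR, with a smallest value of 830 in each thresholded list, the score of an IDR of 0.01. The rankings carry the −log10 of the IDR, as deposited by the authors. Comparison of the files showed that each thresholded list holds the peaks of its ranking at an IDR of at most 0.01, less 212 (main list), 146 (conservative), 99 (replicate 1) and 194 (replicate 2) peaks, and why these are missing is not given in the sources used here. All 7544 peaks of the main list are in a ranking of 100373 peaks, and all 5704 of the conservative list in the ranking of 72370 peaks that matches the replicates. The main list holds 43 repeated intervals with another summit, so that a broad region can count as several peaks, and 1 peak outside the 7 chromosome arms, which was left out of tests by location.

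Genes and TSSs came from the Ensembl release 115 annotation on the same assembly, after checking that the peaks lie within the chromosome lengths. Genome sequence came from the RefSeq copy of that assembly. Transposable elements were left out, which left 18277 genes on the 7 arms, 13968 of them protein-coding. A gene was called bound when a summit of the main list lay within 500 bp of any of its TSSs, and its signal was that of its strongest such peak. Calls at the 5′-most TSS were used for motifs and divergent promoters. A divergent gene has the 5′-most TSS of an opposite-strand protein-coding gene within 500 bp upstream. Reads that map to several near-identical genes (histone, Hsp70 or rRNA copies) can be lost or split before peaks are called, so absence of a peak there is uncertain.

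Shared peaks were counted by an overlap of at least 1 bp. The share of summits near TSSs was set against 1000 random placements within the chromosome, and other location classes against 20. Bound shares were compared with Fisher's exact test, two-sided, with Woolf 95% intervals of the odds ratio, and shares carry Wilson 95% intervals, which cover counting error only. For 27 gene lists, p-values were adjusted over the lists with the Benjamini-Hochberg method, threshold 0.05. The background was all other protein-coding genes. Members were given as symbols or as patterns of symbols: older symbols were matched through RefSeq synonyms (h, Unc-89, Mst35Ba, Mst35Bb and Zw5), rye was not matched, and nos was missed because the annotation holds it as nanos, which was found after the data were seen and tried as an alternative. Median signals were compared on the log2 scale by permutation (100000 permutations, 10000 for motifs and for the signal of lists), two-sided, with bootstrap intervals from 1000 resamples. Consensus strings of 8 core promoter motifs were searched on both strands from 150 bp upstream to 50 bp downstream of the 5′-most TSS. The exceptions were the initiator, searched on the sense strand within 5 bp of the TSS, and the TATA box, from 40 to 15 bp upstream. Each consensus reversed served as a control.

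Named genes followed a rule fixed before the data were examined: all NSL and MSL members, the 20 genes of highest promoter signal bound in both replicates' own lists, per list the 3 bound members of highest signal and up to 3 unbound members in alphabetical order, the 5 strongest peaks over 500 bp from any TSS and the 5 X-linked genes of highest signal. Some gene examples with a nearer neighbour (CG3594, Dhpr and MRG15) were chosen after their values were seen. The gene lists, motifs, tests and most alternatives were likewise fixed before the data were examined. The alternatives were the conservative list, each replicate's own list, a stricter IDR, TSS windows of 250 and 1000 bp, the 5′-most TSS, a background of the 10720 genes with any peak before thresholding, another overlap or list length, a wider motif window (300 bp upstream to 100 bp downstream), unbound promoters matched on GC content and random placement over the whole assembly. An IDR of at most 0.01, planned as the stricter threshold, proved to be that of the lists themselves. An IDR of at most 0.001 (4685 peaks), the stronger 50% by signal (3772 peaks) and 1 peak per 220 bp (6936 peaks) and the assignment of each summit to its nearest 5′-most TSS only, for divergent promoters, were added after the data were seen.

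The steps were tested on simulated data. Of 200 promoters given a peak among 13968 genes, 200 were recovered. These peaks were planted inside the window used for the calls, so this checked the code and not the sensitivity of the calls. With the odds raised 4 times in 10 lists of 20 to 77 members, 91.5% of these lists were called over 100 rounds, and 1.88% of unchanged lists were. Raised odds in smaller lists and lowered odds in any list were not simulated, so the 91.5% does not cover them. A planted motif odds ratio of 4 came back with a median of 4.02 and lay within 20 of 20 intervals. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.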

Results

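MBD-R2 is a chromatin protein of Drosophila melanogaster and a subunit of the NSL (non-specific lethal) complex, which carries the histone acetyltransferase MOF. MOF is also part of the MSL (male-specific lethal) complex, which acts on the male X chromosome in dosage compensation. Chromatin immunoprecipitation with an antibody against GFP was sequenced (ChIP-seq) from whole embryos aged 0 to 24 h of a transgenic line that expresses MBD-R2 fused to eGFP. The series holds 1 group with 2 biological replicates, so the comparisons are between replicates and between classes of genes and peaks, not between conditions. Replicate 1 had 4113 peaks in its thresholded list, with a median signal value of 68.6, and replicate 2 had 7542, with a median of 77.7. Each of these lists came from that replicate's own ranking, not from a comparison of the replicates. The main list, made from both replicates, held 7544 peaks with a median signal of 118 and a median width of 440 bp. A conservative list held 5704. The number of reads behind these lists is unknown here, and each signal value is the authors' own value for that peak. Genes and peaks are not independent replicates, so p-values across them describe these peak lists and not the spread between embryo collections.

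The peaks of replicate 1 were nearly contained in those of replicate 2. Of the 4113 replicate 1 peaks, 3931 overlapped a replicate 2 peak by at least 1 bp (95.6%, Wilson 95% interval 94.9 to 96.2), and 182 did not. In the other direction 4081 of 7542 replicate 2 peaks had a partner (54.1%), which left 3461 peaks in replicate 2 alone. These unshared peaks were weaker, with a median replicate 2 signal of 55.0 against 113 for shared peaks, and they lay at promoters less often. Of the shared replicate 2 peaks, 92.0% (95% interval 91.1 to 92.8) had a summit within 500 bp of a transcription start site (TSS), against 57.3% (55.7 to 59.0) of the unshared ones. Under 7054 main-list peaks, 93.5% of the list, both replicates had a peak of their own before thresholding, and across these peaks the replicate signals had a Spearman correlation of 0.80. The median ratio of replicate 2 to replicate 1 signal there was 1.74 (quartiles 1.36 and 2.32). Across all 72370 peaks of the ranking that compares the replicates this correlation was 0.36, and across the 7747 at an irreproducible discovery rate (IDR) of at most 0.05 it was 0.75. The IDR keeps peaks whose ranks agree in this same comparison, so a higher value there is built into the filter. The shared percentage depended on the definition. It was 71.0% with at least 50% overlap of both peaks and 70.8% between the 1000 strongest peaks of each replicate.

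MBD-R2 was found mainly at promoters. Of 7543 main-list summits on the chromosome arms, 5746 lay within 500 bp of an annotated TSS (76.2%, 95% interval 75.2 to 77.1). The same summits placed at random within their own chromosomes gave a mean of 13.6% and at most 14.8% in 1000 placements (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). The share was 76.1% in the list of replicate 2, but 91.6% in that of replicate 1 and 85.8% in the conservative list, so the share of summits away from TSSs depends on the list. The summits were centred on the TSS itself: 51.6% lay within 100 bp of one, and promoter summits had a median signed distance of -1 bp with quartiles at -61.8 and 53 bp. Introns held 15.8% of summits, against 39.3% of random positions, and intergenic sequence held 5.40% against 27.4%. Coding exons held 1.17% against 13.8%, and positions within 500 bp of a transcript 3′ end but of no TSS held 2.21% against 8.20%. The promoter share fell from 91.9% in the strongest 10% of the peaks to 50.8% in the next-to-weakest. It was 67.4% in the weakest 10%, where most of the weakest peaks sat beside a stronger one: 297 of the 301 peaks with a signal under 20 had a stronger summit within 500 bp.

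**Figure D1:**
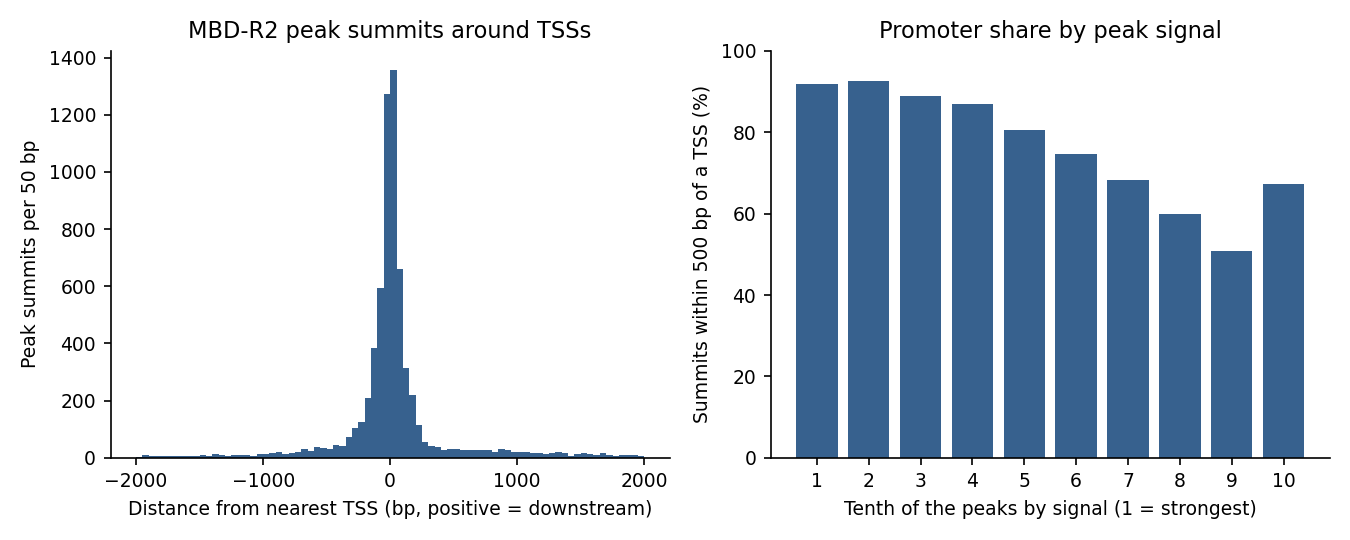
Left, the number of main-list peak summits per 50 bp (vertical axis) by distance from the nearest TSS in bp (horizontal axis, positive downstream), with the pile-up centred on the TSS. Right, the percentage of summits within 500 bp of a TSS in each 10% of the peaks by signal, from 91.9% in the strongest to 50.8% in the next-to-weakest.

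In all, 6151 of 13968 protein-coding genes (44.0%, 95% interval 43.2 to 44.9) had a summit within 500 bp of one of their TSSs and are called bound here. The replicates' own lists gave 4638 and 6070 bound genes, of which 4505 were shared, 97.1% of the genes of replicate 1. Of non-coding RNA genes 325 of 3289 (9.88%) had such a summit, and of tRNA genes 19 of 290 (6.55%). Away from TSSs of coding genes these were 116 of 2353 (4.93%) and 7 of 211 (3.32%), and the difference from coding genes was not tested. The strongest bound promoter was that of Ugalt, a Golgi transporter of UDP-galactose on the X chromosome. Its peak lay at X, 2703680 to 2704087 (dm6), across its TSS, with the summit 33 bp upstream and a signal of 1790.2 (500.3 in replicate 1 and 1294.5 in replicate 2). The uncharacterised gene CG14100 followed with 1649.6. A single peak of 1545.4 at 3R, 29736556 to 29737171, served the divergent pair of CG7601 and CIA30, the latter an assembly factor of respiratory complex I. Among the 20 strongest, mRpL41, a mitochondrial ribosomal protein, had a signal of 1437.3, PNPase, the mitochondrial polynucleotide phosphorylase, 1096.9, mRpS23, which shares its peak with the Arf GTPase regulator CenG1A, 1059.9, and mRpL23, which shares its peak with CG9004, 1027.5. Others were the pair of CHMP2B, an ESCRT-III subunit, and Tcs5 at 1386.5, the pair of CG5611 and Mtl at 1187.3, and eIF6, a factor of ribosome assembly, at 1140.3. The polycomb group gene ph-p had a signal of 1052, the pair of CG9147 and Fbw5 1045.5, and the pair of CG13390 and CG17294 1043.9.

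The genes of the NSL complex itself were all bound, 7 of 7 against 44.0% of other genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.00509 over 27 lists). MBD-R2 carried a peak at its own promoter (3R, 12356027 to 12356466) with its summit 18 bp from a TSS and a signal of 228.5. The fusion transgene carries MBD-R2 sequence, and whether it includes this promoter is not given in the sources used here. The other members were Rcd5 (261.7), dgt1 (214.8), mof (206.1), Rcd1 (165.6), nsl1 (130.5) and wds (71.9). The last 2 had no promoter peak in the replicate 1 list, where 5 of 7 were bound and the list did not pass (adjusted Fisher p = 0.0573). Of the MSL complex, msl-1 (429.1), msl-2 (280.2), mof and msl-3 (168) were bound and mle, the RNA helicase, was not. With 4 of 5 the MSL list did not pass the test (adjusted Fisher p = 0.191). It did pass in the conservative list, where all 5 were bound (adjusted Fisher p = 0.0126).

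Genes of machinery that most cells use were bound far more often than other genes. These genes were chosen by function, and their expression was not measured. Of 27 lists fixed before the data were examined, 14 had a higher bound share than all other protein-coding genes, 10 a lower one and 3 did not pass (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted). The 12 lists of broadly expressed machinery together had 430 of 483 genes bound, against 42.4% of the rest (odds ratio 11.0, 95% interval 8.26 to 14.7). That pooled value was not computed in each replicate's own list. In the replicate 1 list the odds ratio was lower for each of these lists except proteasome subunits, for example 8.09 against 43.4 for aminoacyl-tRNA synthetases. All 20 nucleoporin genes were bound (adjusted Fisher p = 1.66e-07), with Nup205 (363.1), Nup160 (328.6) and Nup50 (328.4) strongest. Aminoacyl-tRNA synthetases had 34 of 35 bound (adjusted Fisher p = 7.99e-11), led by TrpRS (598.4), AlaRS-m (562.4) and beta-PheRS (542.9), and AspRS was the member without a peak. Mitochondrial ribosomal proteins had 70 of 73 (adjusted Fisher p = 9.63e-21), all but mRpL36, mRpL47 and mRpS5. Proteasome subunits had 30 of 32 (adjusted Fisher p = 8.78e-09), with Prosbeta1 (576.9), Rpn10 (527.7) and Rpt4 (496.1) strongest and Prosalpha1 and Rpn7 not bound. The core spliceosome had 28 of 30 (adjusted Fisher p = 3.64e-08), with Prp40 at 496.4, Prp3 at 344.5 and Prp38 at 339.5, and without Sf3b5 and snRNP-U1-70K. DNA replication genes had 34 of 37 (adjusted Fisher p = 4.60e-09), with PolD2 at 477.5, PolA2 at 410.7 and Orc4 at 383.1, and without Mcm7, PolE2 and RPA3.

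The other lists with a higher share cover transcription, insulators, respiration, translation, autophagy and protein folding. The TFIID, Mediator and general transcription factor list had 43 of 48 bound (adjusted Fisher p = 3.40e-10), led by MED10 (412.8), MED30 (411.7) and MED6 (390.1), with MED15, MED26 and Taf3 among those without a peak. Proteins that bind promoters and insulators had 14 of 15 (adjusted Fisher p = 0.000174), led by Chro (690.2), Cp190 (481.2) and ZIPIC (343.7), with su(Hw) not bound. Nuclear-encoded subunits of oxidative phosphorylation had 55 of 68 (adjusted Fisher p = 2.26e-09), with ATPsynF at 560.3, UQCR-C1 at 559.7 and ND-B17 at 406.9, while ATPsynC, ATPsynCF6 and ATPsynbeta were among those not bound. Translation initiation factors had 28 of 35 (adjusted Fisher p = 4.15e-05), led by eIF6, eIF2Balpha (498.3) and eIF3h (481.2), and eIF3d2, eIF3g1 and eIF4A were not bound. Autophagy genes had 15 of 20 (adjusted Fisher p = 0.00837), with Atg9 at 412, Atg7 at 315.5 and Atg6 at 289.5, and without Atg10, Atg101 and Atg18b. The CCT chaperonin had 7 of 8 (adjusted Fisher p = 0.0311), with CCT4 (310), CCT7 (148) and CCT1 (121.5) strongest and CCT3 not bound, and its call was lost in 7 of the 10 alternatives that could change it. Cytosolic ribosomal proteins had 66 of 77 (adjusted Fisher p = 3.61e-13), with RpL7 (632.5), RpL14 (446.8) and RpL34b (421) strongest and RpL10, RpL13A and RpL21 among those not bound. The call was lost in the replicate 1 list, where 31 of 77 were bound and the odds ratio was 1.36 (adjusted Fisher p = 0.208). It was kept in the conservative list, where 54 of 77 were bound (adjusted Fisher p = 1.81e-07).

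**Figure D2:**
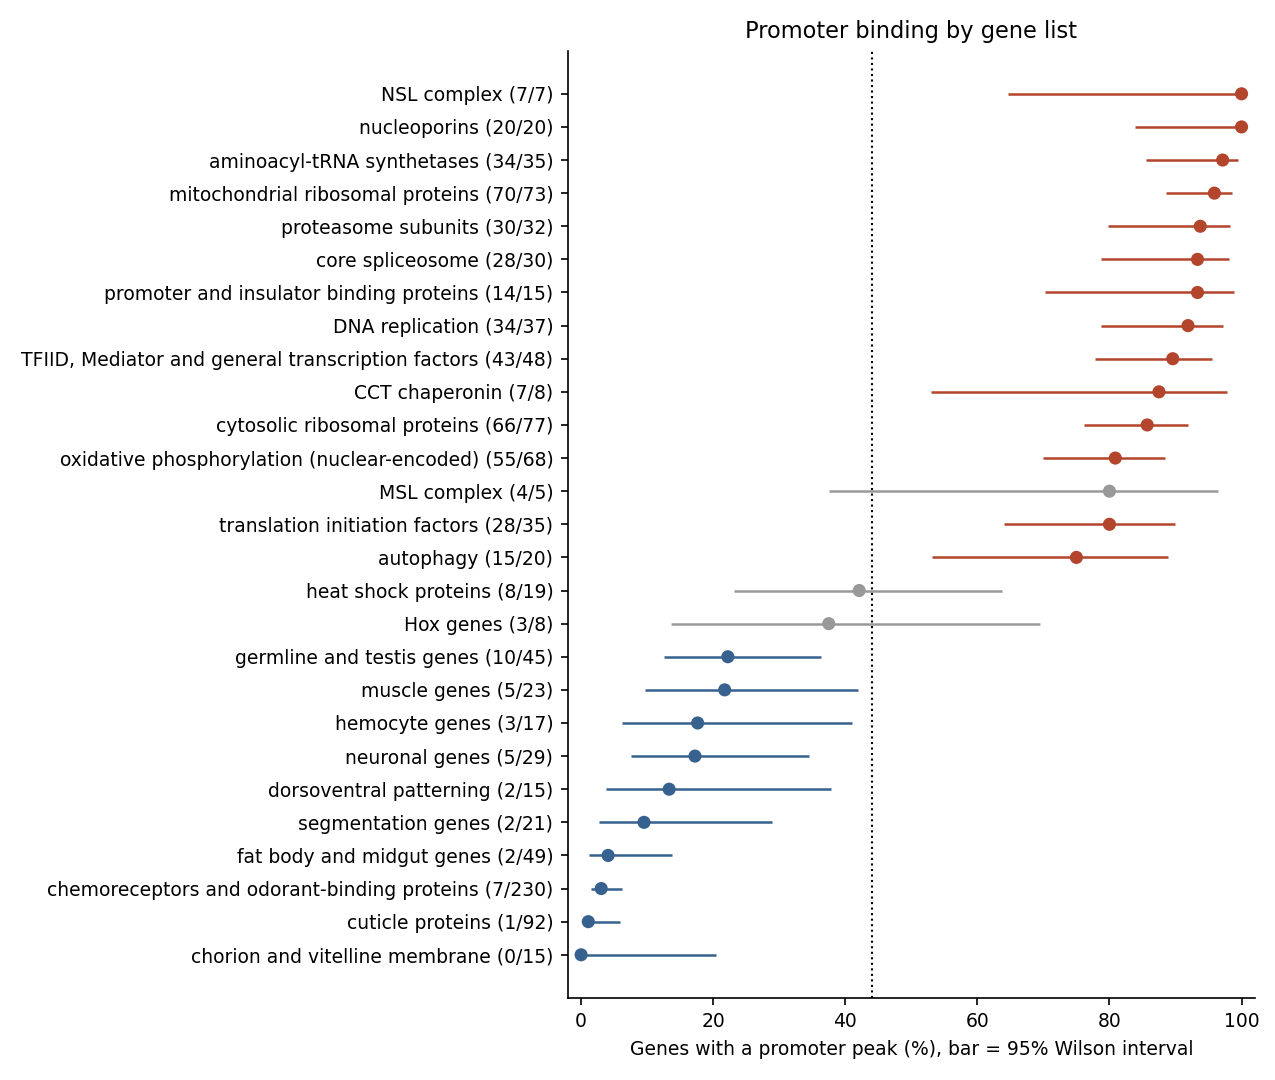
Percentage of protein-coding genes with a promoter peak (horizontal axis) in each of the 27 gene lists, with bound and total members in brackets and 95% Wilson intervals as bars. Red lists were bound more often than other genes, blue lists less often and grey lists did not pass the test; the dotted line marks the 44.0% of all protein-coding genes.

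Genes of segmentation, dorsoventral patterning, neurons, muscle and hemocytes were bound less often than other genes. The 4 lists of embryonic patterning and tissues (segmentation, dorsoventral, muscle and neuronal genes) had 14 of 88 genes bound together (15.9%, odds ratio 0.239, 95% interval 0.135 to 0.423). Segmentation genes had 2 of 21 (adjusted Fisher p = 0.00229): bcd, the maternal anterior determinant (124.2), and hh (64.3), but not Kr, cad or en. Dorsoventral patterning genes had 2 of 15 (adjusted Fisher p = 0.0230), the mesodermal regulators tin (231) and twi (62.5), and bap, brk and dl had no peak. Neither replicate's own list held a promoter peak of hh or twi, while that of replicate 2 held a cad peak (39.0). Neuronal genes had 5 of 29 (adjusted Fisher p = 0.00587). Among them elav, the pan-neuronal RNA-binding protein, had a strong peak (459.5, with 140.4 in replicate 1 and 315.5 in replicate 2), followed by Csp (100.4) and futsch (62.3), while CadN, ChAT and Ddc had none. The elav summit lay 263 bp from a TSS of elav and equally far from a TSS of lncRNA:enrr, so distance does not assign it to either. Muscle genes had 5 of 23 (adjusted Fisher p = 0.0395), with Msp300 at 221.4, Tm1 at 208.5 and sls at 155.5, and the actin genes Act57B, Act79B and Act87E had no peak. Hemocyte genes had 3 of 17 (adjusted Fisher p = 0.0341), the scavenger receptor crq (366.5), PPO3 (212.9) and ush (85.7), and Col4a1, He and Hml had none. Of the 10 alternatives that could change them, the muscle call was lost in 7, the hemocyte call in 5 and the dorsoventral call in 2. Hox genes had 3 of 8, Dfd (73.1), lab (52.5) and Abd-B (51.1), none of them in the replicate 1 list, and heat shock genes had 8 of 19, with Hsp27 at 408.9. Neither list passed (adjusted Fisher p = 1 for both), but in the conservative list, where no Hox gene was bound, the Hox share was lower (adjusted Fisher p = 0.0300).

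Genes of the cuticle, the senses, digestion, the germline and the eggshell were bound less often than other genes too. Cuticle proteins had 1 of 92 (adjusted Fisher p = 5.94e-21), and its summit, 479 bp from a TSS of Lcp9, lay 10 bp from a TSS of CG3594. Chemoreceptors and odorant-binding proteins had 7 of 230 (adjusted Fisher p = 1.45e-45), among them Gr63a (221.5), Ir76a (158.8) and Gr61a (138.2), and Gr10a, Gr10b and Gr21a had none. Fat body and midgut genes had 2 of 49 (adjusted Fisher p = 2.08e-09), Jon25Bi (213.9) and Mal-A5 (157.1), and not the amylases Amy-d and Amy-p. Germline and testis genes had 10 of 45 (adjusted Fisher p = 0.00564), with the meiotic regulator bol at 404, Prosbeta2R2 at 221.6 and bgcn at 215.7, while Mst84Da, Mst84Db and Mst84Dc had none; among genes with any peak before thresholding this list no longer passed (adjusted Fisher p = 0.321). The planned member nos was missed by the symbol match because it stands as nanos in the annotation. It was bound (345.84, summit 405 bp from a TSS), and with it 11 of 46 were bound (adjusted Fisher p = 0.00918). The chorion and vitelline membrane list had 0 of 15 (odds ratio 0.0409, 95% interval 0.00245 to 0.684, adjusted Fisher p = 0.000459), including Cp15 and Cp16. That list was drawn by symbol and also took in Cp110, a centriolar protein. Across all lists that were bound less often, 17 of 37 bound members had a summit nearer to a TSS of another gene (45.9%), such as CG3594 for Lcp9, Dhpr for bol and MRG15 for Tm1. In the broadly expressed lists this held for 107 of 430 (24.9%). Of the genes named above, the summits of Gr63a, Ir76a, Gr61a, Jon25Bi, Prosbeta2R2 and PPO3 also lay nearer to a TSS of another gene. Those of Mal-A5, bgcn, crq and ush did not.

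On the X chromosome slightly more genes were bound than on the autosomes, with weaker peaks. Of 2196 X-linked protein-coding genes 47.4% were bound, against 43.6% of 11669 genes on 2L, 2R, 3L and 3R (odds ratio 1.17, 95% interval 1.07 to 1.28, two-sided Fisher's exact test, p = 0.000958). The median signal of promoter peaks was 119 on the X (1011 peaks) and 141 on the autosomes (4707 peaks), a log2 difference of -0.24 (95% bootstrap interval -0.33 to -0.18). That difference had p = 1e-05 in a two-sided permutation test, the smallest that 100000 permutations can give. The X-linked genes of highest signal were Ugalt, ph-p, MFS10 (759.7) and the divergent pair of c12.1 and c12.2 (748.3). On chromosome 4, 25 of 80 genes were bound (31.3%, 95% interval 22.2 to 42.1) with a median signal of 91.5, and on the Y none of 23 was, where the interval reaches 14.3%. The signal difference had the same sign in both replicates' own lists, -0.22 in replicate 1 and -0.25 in replicate 2. The difference in the share of bound genes was not stable: in the replicate 1 list the odds ratio was 1.00 (Fisher p = 0.961), and with the stronger 50% of the peaks, chosen after the data were seen, it turned to 0.858 (p = 0.00259).

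**Figure D3:**
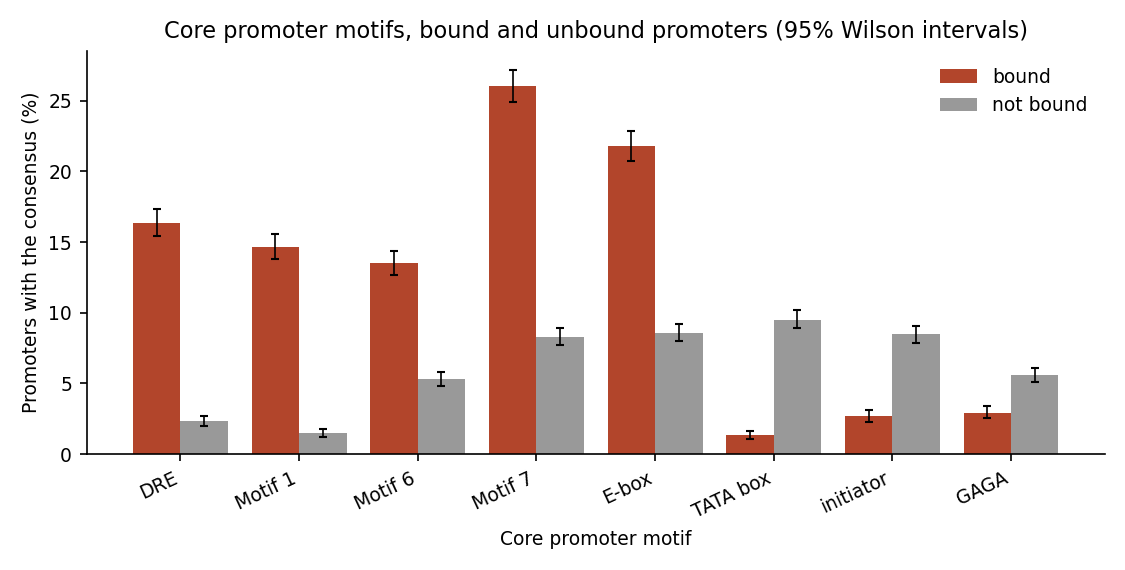
Percentage of promoters with each core promoter motif (vertical axis) among 5869 bound (red) and 8099 unbound (grey) 5′-most TSSs of protein-coding genes, with 95% Wilson intervals. The motifs on the left, DRE, Motif 1, Motif 6, Motif 7 and E-box, were more frequent in bound promoters, while TATA box, initiator and GAGA were less frequent.

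Bound promoters carried other core promoter motifs than unbound ones. The 5′-most TSSs of 5869 genes were bound and those of 8099 were not. Of the bound ones 2803 belonged to divergent genes, of which 80.5% were bound, against 29.2% of single genes. In a divergent pair the same motif site can lie in the windows of both genes and count more than once. The intervals and p-values of the motif tests may therefore be too small, and the odds ratios were not adjusted for divergence. The DRE (TATCGATA), the site of the factor Dref, occurred within 150 bp upstream to 50 bp downstream of 16.3% of bound and 2.32% of unbound promoters (odds ratio 8.22, 95% interval 7.001 to 9.648). Motif 1 (GGTCACAC), the site of M1BP, occurred in 14.7% against 1.47% (odds ratio 11.5, 9.49 to 14.0). Motif 7 (CAKCNCTR), in 26.0% against 8.30% (3.89, 3.53 to 4.29), the E-box CAGCTG, in 21.8% against 8.58% (2.97, 2.69 to 3.28), and Motif 6 (GTATWTTT), in 13.5% against 5.28% (2.80, 2.47 to 3.16), were more frequent too. At least 1 of these 5 motifs occurred in 66.1% of bound and 22.8% of unbound promoters. Motifs of regulated promoters went the other way. The TATA box at its usual place occurred in 1.33% of bound against 9.51% of unbound promoters (odds ratio 0.128, 0.101 to 0.162), the initiator in 2.68% against 8.47% (0.297, 0.249 to 0.354) and GAGA repeats in 2.93% against 5.61% (0.508, 0.425 to 0.608). Seen from the motif, 83.6% of 1147 promoters with a DRE and 87.9% of 980 with Motif 1 were bound, and 9.20% of 848 with a TATA box. Each of the 8 differences passed Fisher's exact test with Benjamini-Hochberg adjustment, with adjusted p from 6.99e-210 for Motif 1 to 1.61e-14 for GAGA. In the replicate 1 list the odds ratios were 5.33 for Motif 1, 5.22 for the DRE, 0.257 for GAGA and 0.189 for the initiator, so the sizes of these differences depend on the list. Against unbound promoters matched on GC content the GAGA odds ratio was 0.768 (adjusted Fisher p = 0.0134).

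The DRE and Motif 1 were the motifs most concentrated at promoter summits. Within 100 bp of promoter summits the DRE occurred at 11.2% of peaks against 0.618% of flanks 1000 bp away, and Motif 1 at 10.9% against 0.522%, ratios of 18.2 and 20.9. The ratios of the other motifs were 2.77 for Motif 7, 2.46 for Motif 6, 1.74 for the E-box, 1.37 for the TATA box, 1.25 for GAGA and 1.08 for the initiator, searched here on both strands and anywhere in the window, and none of these ratios was tested. At summits away from TSSs these were 0.890% against 0.890% for the DRE and 0.723% against 0.640% for Motif 1. Promoter summits lie within 500 bp of a TSS by definition, and the flanks lie 1000 bp away. Core promoter motifs can differ between such places at any promoter, and unbound TSSs were not measured in this way. The ratios therefore do not separate position at a TSS from binding. Among bound promoters those with an E-box had a higher signal than those without (log2 difference 0.40), as had those with Motif 7 (0.26). Bound promoters with a TATA box (-0.49), an initiator (-0.53), GAGA (-0.73) or Motif 6 (-0.15) had a lower one, with adjusted p from 2.00e-04 to 4.00e-04 in permutation tests. For the DRE and Motif 1 no difference in signal was found (adjusted permutation p = 0.289 and 0.216). As a control each consensus was also searched in reversed order. The reversed DRE had an odds ratio of 2.40 (1.48 to 3.89) and the reversed Motif 1, CACACTGG, of 6.31 (4.56 to 8.74). The reversed strings of these motifs were therefore enriched themselves, to a smaller degree, and of the 200 bound promoters with the latter string 127 also held Motif 1 itself. Without promoters that hold Motif 1 the odds ratio of that string was 3.36. The reversed E-box was less frequent in bound promoters (0.563, 0.459 to 0.690), against the direction of the E-box itself. The reversed Motif 6 (1.06), Motif 7 (1.08), TATA box (1.06) and initiator (1.67, adjusted Fisher p = 0.0681) did not pass. GAGA reads the same reversed and has no such control.

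Genes that share a divergent promoter were bound more often than single genes, by a margin that depends on how shared summits are counted. Of 3483 genes with the 5′-most TSS of an opposite-strand protein-coding gene within 500 bp upstream, 2803 were bound at their own 5′-most TSS (80.5%), against 3066 of 10485 single genes (29.2%). The odds ratio was 9.97 (95% interval 9.08 to 11.0), and Fisher's exact test gave a p below the smallest number the software can hold. The pairs of CG7601 with CIA30, CHMP2B with Tcs5 and mRpL23 with CG9004 are examples among the strongest. Bound divergent promoters also had a higher median signal, 201 against 148 (log2 difference 0.45, 95% bootstrap interval 0.39 to 0.51, permutation p = 1e-05, the smallest possible). Both genes of a pair can take their signal from the same peak, so such peaks can count more than once and the interval may be too narrow. A window around a divergent TSS often takes in the TSS of the partner, and 2 independent windows at the share of single genes would give 49.9% and an odds ratio of 2.41. The observed share and odds ratio, 80.5% and 9.97, lay above these values. With each summit assigned only to its nearest 5′-most TSS, a control chosen after the result was seen, 1656 divergent (47.5%) and 2906 single genes (27.7%) were bound, an odds ratio of 2.36 (2.18 to 2.56, Fisher p = 4.85e-100). By construction a shared peak then counts for only 1 gene of a pair. The fall therefore does not show that the difference was an effect of the window.

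Peaks at promoters had a higher signal than peaks elsewhere, with medians of 136 at 5746 promoter peaks and 79.8 at 1797 others (log2 difference 0.77, 95% bootstrap interval 0.72 to 0.82, permutation p = 1e-05, the smallest possible). The strongest peak of the whole list was nonetheless not at an annotated TSS. It lay in an intron of CG11050 at 2L, 6612521 to 6613079, 1018 bp from the nearest TSS, with a signal of 1824.3. The next 4 peaks away from TSSs were intronic as well. They lay in CG9663 (2L, 3301985 to 3302350, signal 964.4), CG32772 (X, 4910205 to 4910527, 844.9), Adf1, a sequence-specific transcription factor (2R, 6662904 to 6663224, 787.2), and Trl, which encodes GAGA factor (3L, 14759336 to 14759695, 786.1). Their summits were 807 to 1525 bp from the nearest TSS of the same gene. Distal peaks were found in replicate 1 less often than promoter peaks: 341 of 1797 overlapped a peak of the replicate 1 list, against 66.4% of promoter peaks, while in the replicate 2 list these were 77.2% and 91.8%. The log2 difference between promoter and other peaks shrank to 0.39 in the replicate 1 list and in the conservative list, and stayed past the threshold in both.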

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

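Of 502 alternative values, 429 could differ from the main value by construction. Of them, those with an IDR of at most 0.001, the stronger 50% of peaks or 1 peak per 220 bp, with nanos added to the germline list or with each summit given to its nearest TSS were chosen after seeing the data, and an IDR of at most 0.01 left the list as it was and says nothing. The share of replicate 1 peaks found in replicate 2 was 83.0% with lists of equal length, 71.0% with 50% overlap of both peaks, 84.9% with summits within 100 bp and 70.8% for the 1000 strongest peaks. The Spearman correlation of the replicate signals rose from 0.36 to 0.75 among peaks at an IDR of at most 0.05. That filter selects peaks whose ranks agree between the replicates, so the rise is not separate evidence of agreement. The odds ratio of X-linked against autosomal genes reversed to 0.950 (Fisher p = 0.308) at an IDR of at most 0.001 and to 0.858 (p = 0.00259) with the stronger 50% of peaks. It was 1.01 (Fisher p = 0.835) among genes with any peak before thresholding, and leaving out each replicate gave 1.00 to 1.12; the cause was not tested. Of the gene list tests, 244 of the 271 alternatives that could change had the same call, 24 lost it and 3 gained it. The odds ratios of heat shock (0.924 to 1.98) and Hox genes (0.762 to 1.11), neither past the threshold, crossed 1 among genes with any peak before thresholding. The lost calls were those of the CCT chaperonin, muscle, hemocyte and dorsoventral lists, of germline and testis genes, of the NSL complex and of cytosolic ribosomal proteins, the last 2 only without replicate 2. All 62 motif alternatives that could change kept direction and call, but without replicate 2 the odds ratio fell from 11.5 to 5.33 for Motif 1 and from 8.22 to 5.22 for the DRE, and GAGA moved from 0.508 to 0.257 and the initiator from 0.297 to 0.189, while GC-matched unbound promoters brought GAGA to 0.768; the cause was not tested. The promoter share of summits rose from 76.2% to 91.6% without replicate 2. The lower signal on the X ranged from -0.18 to -0.30 over its 9 alternatives. The odds ratio of divergent promoters ranged from 8.32 to 10.6, but fell to 2.36 with each summit given to its nearest TSS only, since by construction a shared peak then counts once. No paired analysis was possible because there is 1 group. The unknown depth limits what absence from the replicate 1 list means, since 77.0% of the replicate 2 peaks without a partner are in the replicate 1 ranking.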

Other observations

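The tests of signal ratios by location, of X-linked ranks, of divergent promoters on the X and of the Zelda site were chosen after the main results had been seen, though before their own values. The test of the promoter share at matched signal was chosen after related values had been seen. No explanation that needs a comparison of conditions was tested, because the design has 1 group.

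Bound cytosolic and mitochondrial ribosomal protein genes differed in signal. Bound cytosolic ribosomal protein genes had a median signal of 124 (66 genes) and mitochondrial ones of 237 (70 genes), a log2 difference of -0.94 (95% bootstrap interval -1.11 to -0.69, permutation p = 1e-05, the smallest possible). The difference had the same sign in the lists of replicate 1 (-0.65, interval -0.87 to -0.19), where only 31 of 77 cytosolic genes were bound, and replicate 2 (-0.67, interval -0.95 to -0.41). Against all other bound genes the cytosolic list was lower by a log2 difference of -0.46 (adjusted p = 0.00760) and the mitochondrial list higher by 0.49 (adjusted permutation p = 0.00760), with 19 lists compared. The TFIID and Mediator list was higher too (0.46, adjusted permutation p = 0.0347), and the 5 bound neuronal genes were lower (-1.45, interval -2.81 to 1.43, adjusted p = 0.00760), an interval that spans 0 because elav is far above the rest. The E-box CAGCTG occurred in 39 of 73 mitochondrial and 5 of 77 cytosolic ribosomal promoters, the DRE in 15 and 22 and Motif 1 in 8 and 12. These signal comparisons were chosen after the bound shares were seen.

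The genes with most distal peaks were sbb with 12 summits over 500 bp from any TSS, CG32264 with 10, CHES-1-like with 9, and Tlk and ush with 8 each, counts that were not set against gene length. In all, 898 protein-coding genes held at least 1. The hypothesis that distal peaks may lie at early embryonic enhancers was tested with the site of Zelda, a factor that opens enhancers in the early embryo. Its site occurred 1.41 times as often within 100 bp of distal summits as in flanks (95% interval 0.889 to 2.26, adjusted Fisher p = 0.562 over 7 motifs), which leaves the question open. The core of the Su(Hw) site had a ratio of 1.76 (1.13 to 2.89, adjusted Fisher p = 0.109), and GAGA, Grainyhead, Twist, DRE and Motif 1 sites had ratios from 0.857 to 1.13.

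Base composition of bound promoters as the whole cause of the enriched DRE is argued against by its reversed consensus, whose odds ratio of 2.40 (1.48 to 3.89) lay below that of the DRE (8.22), but it could account for a part.

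Replicate 2 had 1.83 times as many thresholded peaks as replicate 1, and a lower depth or enrichment of replicate 1 is a candidate explanation. A share of 77.0% of its unshared peaks overlapped a peak of the unthresholded replicate 1 ranking, against 20.2% at random places, and as 77.0% lies between the bounds of 50% and 80% set beforehand, that test alone left it undecided. A loss that scales all peaks alike is argued against, both as a shared ranking and as a shared factor: at matched signal in the main list, the log2 ratio of replicate 2 to replicate 1 signal was 0.40 higher at distal than at promoter peaks (95% interval 0.35 to 0.44), though lower depth may still account for a part. The promoter share of unshared replicate 2 peaks lay -34.6 percentage points (interval -36.5 to -32.8) from that of shared ones, a gap to which their lower signal alone could contribute, but at matched pooled signal it was still -27.7 points (interval -32.0 to -23.1, 2726 unshared peaks), in line with replicate 2 holding more peaks away from promoters at equal signal. Whether this comes from the chromatin preparation, the control used or the age mix of the embryos stays open.

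Genes of the broadly expressed lists were bound more often than other genes. The 5721 bound genes outside these lists were not classed by expression. Gene density, which can put the bound promoter of a neighbour within the window, is argued against by isolated genes: with no TSS of another gene within 1000 bp, 92 of 109 broadly expressed genes were bound, with an odds ratio of 16.1 (9.56 to 27.1). GC content is argued against by the odds ratio within GC bins, 8.96 (6.74 to 11.9). Enrichment at any promoter active in embryos would have the patterning and tissue lists bound at least as often as other genes. Their odds ratio was 0.239 (0.135 to 0.423). Signal from any source, MBD-R2 or not, at promoters used in few cells could be diluted in whole embryos. Expression was not measured, so this test cannot decide, and the explanation stays open.

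Promoter peaks on the X had a lower signal, and the lower copy number of the X in a mix of male and female embryos is a candidate explanation, since it would give a uniform shift of -0.42 on the log2 scale. At equal ranks of genes the X minus autosome difference was -0.38 among the top 5% (95% interval -0.45 to -0.28), -0.40 at 10% (-0.47 to -0.30), -0.29 at 20% (-0.37 to -0.20), -0.19 at 30% (-0.29 to -0.10) and 0.11 at 40% (-0.08 to 0.27). The interval excluded the uniform shift at 3 of the 5 ranks, which argues against it as the whole cause, while at the top 10% a shift of that size is not excluded. Fewer divergent promoters on the X (23.2% against 25.4% of genes) are argued against, because the difference was -0.41 (-0.53 to -0.31) within divergent and -0.27 (-0.35 to -0.18) within single promoters. A copy number shift combined with a larger share of bound genes on the X, and the scaling by the control, stay open, since the sex of the embryos was not recorded per the labels.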
